A study of Mus musculus with 10 samples.

How the data were processed

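RNA of sorted splenic NK cells, resting or after 24 h with 100 ng/mL IL-15, and of bulk splenocytes was hybridised to 1-colour Affymetrix MOE430_2 arrays. Per the labels' protocols, NK samples were amplified by a 2-cycle and splenocyte samples by a 1-cycle procedure. The table the authors deposited holds 1 linear intensity per probe set and array, made with GCOS 1.4 per the submitters' processing notes. The summary algorithm and the scaling target are not given in the sources used here. In the deposited table, the mean signal after trimming 2% at each end lay between 1499.5 and 1500.6 on every array, so the arrays had been scaled to a common mean, and no further scaling was applied. Scaling of this kind gives relative levels within an array and hides a change in total RNA per cell.

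The floor was the median over the 10 arrays of each array's 40th percentile, 179.8 signal units. Lower signals were set to it, and log2 was taken. Of the probe sets of genes chosen from unrelated tissues, 18% of values lay above the floor, from 5.2% to 24% per array. A gene was tested in a comparison if it was above the floor on at least 3 arrays of the groups compared. Folds are ratios of geometric means, taken from differences of mean log2 signals. Where a named gene lay at the floor on any array of its dimmer group, its fold is a lower bound and is given as at least N-fold, with the number of arrays above the floor, and group means that include floored arrays are upper bounds. The annotation, GEO's platform table, gave 34958 probe sets with 1 gene symbol, 932 with several and 9211 with none, and 64 control probe sets were left out. Of the single-gene probe sets, 34754 matched the RefSeq gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols needed updating. Each of 18193 genes was represented by its probe set with the highest mean log2 signal over all arrays. Among named genes that passed and had other tested probe sets, all of the others made the same call for 26 of 51 genes in IL-15 NK against resting NK, 12 of 23 in resting NK against splenocytes and 21 of 29 in IL-15 NK against splenocytes. Klrb1c and Il2rg have no probe set assigned to them alone in this annotation and are not analysed here.

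Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2-sided, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). IL-15 NK and resting NK cells were compared over their 6 arrays with no replicate block. For comparisons with splenocytes all 3 groups shared 1 variance. The 4 chips come from 2 biological samples, and the sources used here do not say which belong together. The chips were therefore averaged in pairs under each of the 3 possible pairings, and the largest p of the 3 fits was kept before adjustment. Means and SDs for splenocytes are over 4 chips. Gene lists were tested with camera in limma with a preset inter-gene correlation of 0.01 and again with the correlation estimated, adjusted over the lists of a comparison. The lists held 805 symbols, of which 719 were on the array. The camera calls that held with the estimated correlation were 4 of 16 in resting NK against splenocytes, and 0 of 20 and 0 of 12 in IL-15 NK against resting NK and IL-15 NK against splenocytes, where 10 and 9 had an unadjusted p under 0.05.

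The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes 10 genes chosen in advance (Gzma, Gzmb, Prf1, Ifng, Il2rb, Il2rg, Il2ra, Il15ra, Klrb1c and Ncr1), the 10 largest differences each way between IL-15 NK and resting NK cells, and the 5 largest each way in each splenocyte comparison, among genes past the threshold without overlap between the groups and above the floor on at least 1 array of each group. Predicted genes, RIKEN clones and expressed sequences were left out of this part. From each list it takes up to 4 members past the threshold with the largest differences, or its 2 brightest members where fewer than 2 pass. The text names part of the genes the rule gives.

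The fits were tested on simulated data with 200 changed genes per comparison. In the data far more genes passed, 3003 of 11433 for IL-15 NK against resting NK. A smaller unadjusted p was therefore needed to pass in the simulations, and the shares recovered there do not measure recovery in the data. For IL-15 NK against resting NK, 77.6% of 4-fold, 19.2% of 2-fold and 0% of 1.5-fold changes were recovered over 11433 genes. For resting NK against splenocytes, 48.4%, 10% and 0% were recovered over 12938 genes, and for IL-15 NK against splenocytes 66.2%, 20% and 1.5% over 12465 genes. Of the calls made in these simulations, 1.5%, 7.3% and 7.9% were of unchanged genes, in the same order, which were 1, 3 and 5 genes. The shares for the splenocyte comparisons lie above the level that the threshold of 0.05 aims at. Each share rests on 1 simulated draw, and the spread between splenocyte chips was assumed in it. Alternatives covered normalization, floor, filter, probe set, variance model, threshold, treatment of the splenocyte chips, samples in the fit, a replicate block and leaving out each array in turn.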

Results

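Gene expression was measured on Affymetrix MOE430_2 arrays in natural killer (NK) cells and splenocytes of C57Bl/6 mice. NK cells are lymphocytes that kill infected or transformed cells with granzymes and perforin, and IL-15 is a cytokine that keeps them alive and activates them. NK cells were sorted from spleen as NK1.1-positive, CD3-negative cells. The series held 3 arrays of resting NK cells lysed directly after the sort, 3 arrays of NK cells kept for 24 h with 100 ng/mL IL-15, and 4 arrays of bulk resting splenocytes. Per the series' design text, the NK arrays of each condition were 3 biological replicates and the 4 splenocyte arrays were 2 biological samples with 2 chips each. Each array gave 45101 signals. Above a floor of 179.8 signal units lay 57.8% to 61.7% of them on resting NK, 51.1% to 56.5% on IL-15 NK and 61.2% to 62.4% on splenocyte arrays. Every resting NK array thus had more signals above the floor than any IL-15 NK array, although all were scaled to a common mean. Arrays of a group differed by a median absolute log2 difference of 0.31 to 0.42 in resting NK cells, 0.27 to 0.32 in IL-15 NK cells and 0.22 to 0.31 in splenocytes, and no 2 arrays held identical values. The number of arrays limits the precision. No sample of NK cells cultured without IL-15 was analysed here, so each difference between IL-15 NK and resting NK cells is also a difference between 24 h of culture and none.

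Comparing IL-15 NK with resting NK cells asks which transcripts changed when resting cells were activated. Higher transcripts included those of cell division, sterol synthesis and nutrient uptake. Sqle, an enzyme of cholesterol synthesis, was at least 41-fold higher in IL-15 NK cells (log2 difference at least 5.36 ± 0.24 SE, n = 3 arrays per group, limma adjusted p = 5.1e-06). Tk1, thymidine kinase, was at least 35.1-fold higher (limma adjusted p = 7.0e-06), and Cdc6, which loads the replicative helicase onto DNA, was 29.9-fold higher (limma adjusted p = 1.1e-05). The subunit of an amino acid transporter encoded by Slc7a5 was at least 24.3-fold higher. Sqle, Tk1 and Slc7a5 lay above the floor on 2 of 3 resting arrays each, so their folds are bounds. The transcription factor gene Fos was 34.7-fold lower after IL-15 (log2 difference -5.12 ± 0.35 SE, n = 3 arrays per group, limma adjusted p = 1.6e-05), and the chemokine receptor gene Cx3cr1, above the floor on 1 of 3 IL-15 NK arrays, was at least 18.4-fold lower. Of 11433 genes tested, 3003 changed at an adjusted p under 0.05 in limma, 1619 of them higher and 1384 lower. At least 2-fold differences were found in 1096 higher and 844 lower genes. Over all probe sets singly the balance turned, with 2828 higher and 3545 lower. Without IL-15 NK replicate 3 the count was 1963, with 841 lower genes, and without IL-15 NK replicate 1 there were 853 lower genes. When genes brighter in splenocytes than in resting NK cells were left out, a setting chosen after seeing the data, 926 lower genes were counted. Brighter in splenocytes, here and below, goes by the group means alone, without a test. A sign of RNA or labelling quality moved with the groups: the 3-prime signal of the Gapdh control was 7-fold its 5-prime signal in resting and 3.46-fold in IL-15 NK cells, and that of Actb 3.69-fold and 1.35-fold, with each ratio higher on every resting array than on any IL-15 NK array.

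Among transcripts of the cytotoxic machinery, Gzma, Prf1 and Gzmb had high signals in resting NK cells, while Gzmc was dim. Genes of this machinery moved in different directions after IL-15. Gzmb, granzyme B, rose 2.52-fold from a mean log2 signal of 15.33 ± 0.09 (SD, n = 3) to 16.66 ± 0.30 (SD, n = 3; limma adjusted p = 0.00098). Gzmc, granzyme C, above the floor on 2 of 3 resting arrays, rose at least 12.9-fold from 8.32 ± 0.82 to 12.00 ± 0.39 (SD, n = 3 each, limma adjusted p = 0.00019). Gzma, granzyme A, had means of 17.47 ± 0.28 in resting and 16.95 ± 0.18 in IL-15 NK cells (SD, n = 3 each), a difference that did not pass (limma adjusted p = 0.098). The largest signal of any probe set was 177504.1 to 270300.9 on resting NK and 128232.8 to 153822.4 on IL-15 NK arrays. As unlogged signals, Gzma lay near this top in both groups, and Gzmb after IL-15 lay not far below it. Whether their differences were compressed there was not tested. Prf1, perforin, had means of 16.28 ± 0.28 and 15.92 ± 0.20 (SD, n = 3 each) and did not pass either (limma adjusted p = 0.23). Gzmm, granzyme M, fell by 1.34 on the log2 scale (limma adjusted p = 0.0048). Of 20 cytotoxic granule genes tested, 2 rose, 4 fell and 14 did not pass, and 3 rose and 4 fell when adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.81), and its median of -0.07 and mean of 0.09 differed in sign. Of 13 NK markers 2 rose and 3 fell, and 2 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.33).

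**Figure D1:**
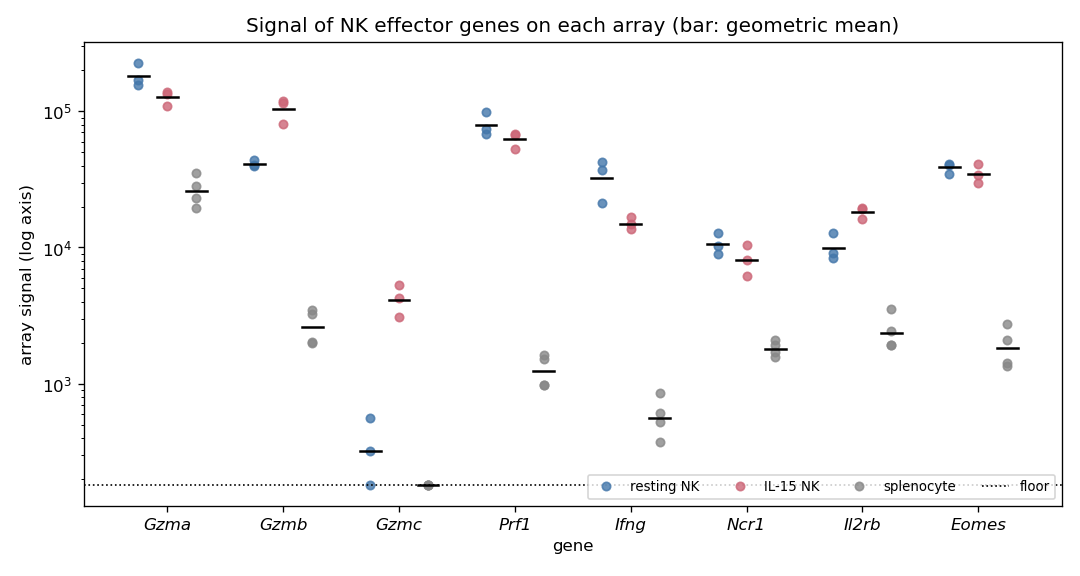
Array signal on a log axis for 8 NK genes; each point is 1 array, bars are geometric means, and the dotted line is the floor of 179.8 to which lower signals were set. Gzmb was 2.52-fold and Gzmc at least 12.9-fold higher in IL-15 NK than in resting NK cells, and all 4 splenocyte chips lay at the floor for Gzmc.

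Ifng, the gene of interferon gamma, fell 2.15-fold after IL-15 from a mean log2 signal of 14.97 ± 0.53 to 13.87 ± 0.15 (SD, n = 3 each, limma adjusted p = 0.0091). The chemokine gene Ccl5 fell by 1.81 on the log2 scale and Ltb, lymphotoxin beta, fell by 1.66. Of 14 cytokine and chemokine genes, 4 rose and 4 fell, and 5 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.80 for the list). Among 15 cytokine receptor genes, 3 rose and 4 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.80). Il2rb, which encodes the beta chain shared by the IL-2 and IL-15 receptors, rose 1.84-fold (limma adjusted p = 0.0090). Il12rb1, a chain of the IL-12 receptor, rose by a log2 difference of 1.92, and Il7r, the IL-7 receptor alpha chain, fell 7.64-fold. Il15ra differed by 0.20 and Il2ra by 0.62 on the log2 scale, the latter above the floor on 2 of 3 resting arrays, and neither passed (limma adjusted p = 0.65 and 0.31). With every gene tested, including the dim ones, Ifng, Ltb and Il2rb no longer passed (limma adjusted p = 0.10, 0.12 and 0.064). Among 18 target genes of STAT5, the transcription factor that IL-15 receptor signals activate, 6 rose and 4 fell, and 7 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.13). Pim2, a kinase, rose by 2.22 and Cish, a feedback inhibitor of cytokine signals, by 2.13, while Bcl6, a transcriptional repressor, fell by 2.50 on the log2 scale.

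Genes of DNA replication and mitosis rose together. Of 43 DNA replication genes 41 rose and none fell, with a median log2 difference of 2.09, and 42 rose when adjusted over the list alone (camera adjusted p = 2.5e-27; adjusted p = 0.12 with an estimated correlation). Of 36 mitosis genes 35 rose and none fell, with a median of 2.89, and 35 rose when adjusted over the list alone (camera adjusted p = 1.9e-29; adjusted p = 0.12 with an estimated correlation). Uhrf1, which maintains DNA methylation at replication, rose by 3.97, Aurkb, aurora kinase B, by 4.58, Bub1, a spindle checkpoint kinase, by 4.19 and Ccna2, cyclin A2, by 3.90 on the log2 scale. The values of Aurkb and Bub1 are lower bounds, as each lay above the floor on 2 of 3 resting arrays. These are values for groups of 3 arrays, and limma's adjusted p was 1.7e-05 or lower for each. The 3-prime to 5-prime ratios of Gapdh and Actb were higher on the resting arrays by log2 differences of 1.02 and 1.45.

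Most tested genes of ribosome biogenesis and cholesterol synthesis also rose. Of 39 ribosome biogenesis genes 38 rose, with a median log2 difference of 1.37, and all 39 rose when adjusted over the list alone (camera adjusted p = 1.0e-20; adjusted p = 0.12 with an estimated correlation). Nop58, a nucleolar protein that modifies ribosomal RNA, rose by 2.21, and Rrp9, which takes part in processing it, by 3.09 on the log2 scale. The list of ribosomal protein genes had a median of 0.07, with 3 of 26 higher and 1 lower both over all genes and adjusted over the list alone (camera adjusted p = 0.62). Of 19 cholesterol synthesis genes 17 rose, and 19 when adjusted over the list alone, with a median of 1.73 (camera adjusted p = 6.8e-14; adjusted p = 0.053 with an estimated correlation). Idi1, isopentenyl diphosphate isomerase, rose by 4.00 on the log2 scale (limma adjusted p = 1.1e-05). Of 21 tRNA synthetase genes 14 rose, and 19 when adjusted over the list alone (camera adjusted p = 5.7e-07; adjusted p = 0.17 with an estimated correlation), among them Rars by 1.66 and Iars by 1.62. Of 19 translation initiation genes 9 rose, and 11 when adjusted over the list alone (camera adjusted p = 0.00016; adjusted p = 0.17 with an estimated correlation), with Eif4a1, an RNA helicase, higher by 2.03. On the same arrays the Gapdh ratio of 3-prime to 5-prime signal was higher by 1.02 in resting cells.

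**Figure D2:**
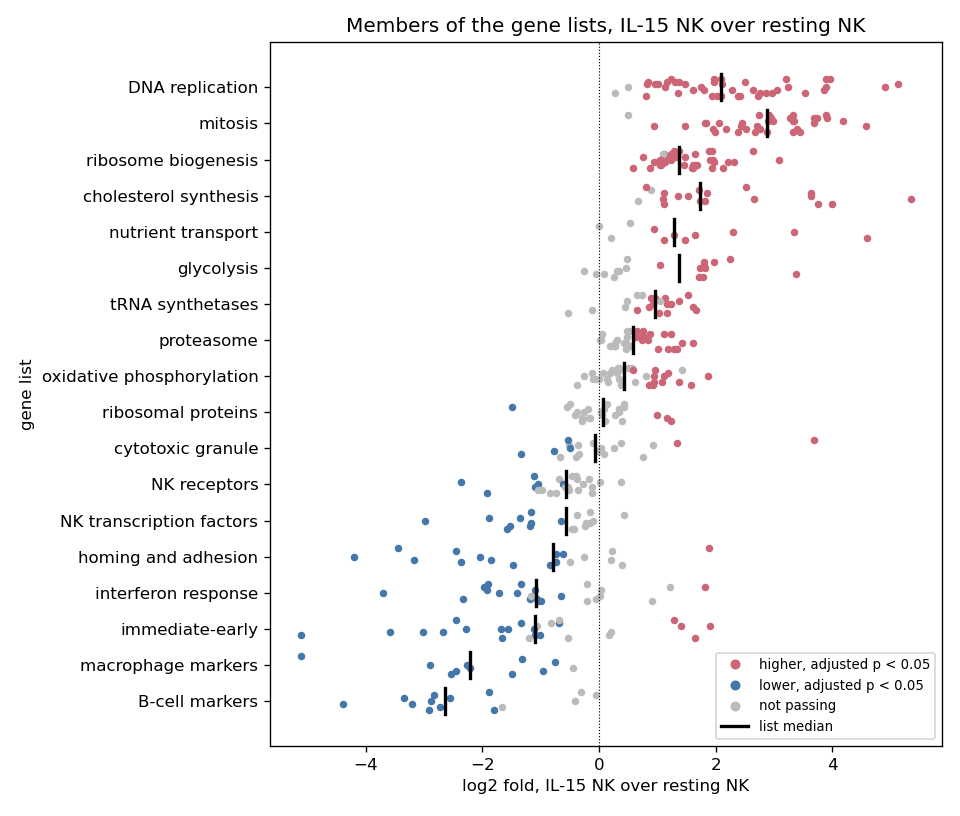
Log2 difference of IL-15 NK over resting NK cells for each tested member of 18 gene lists; points are genes, coloured by their call in limma, and black bars are list medians. Medians ran from 2.89 for mitosis to -2.64 for B-cell markers; genes with arrays at the floor are drawn at their bound.

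Among metabolic genes, 10 of 18 glycolysis genes rose and none fell, with a median log2 difference of 1.38, and 10 rose when adjusted over the list alone (camera adjusted p = 3.4e-06; adjusted p = 0.26 with an estimated correlation). Slc16a1, a lactate transporter, rose by 2.25, Pkm, pyruvate kinase, by 1.97 and Tpi1, triose phosphate isomerase, by 1.81. Of 11 nutrient transport genes 8 rose, as when adjusted over the list alone (camera adjusted p = 7.6e-06; adjusted p = 0.12 with an estimated correlation), and Tfrc, the transferrin receptor, was 10.2-fold higher. Of 34 oxidative phosphorylation genes 12 rose, and 14 when adjusted over the list alone (camera adjusted p = 6.8e-05; adjusted p = 0.28 with an estimated correlation). The ATP synthase genes Atp5g1 and Atp5b rose by 1.87 and 1.38. Of 32 proteasome genes 16 rose, and 20 when adjusted over the list alone (camera adjusted p = 8.4e-07; adjusted p = 0.17 with an estimated correlation), among them Psmd1 by 1.62. Of 27 genes of the endoplasmic reticulum and the unfolded protein response 13 rose and 2 fell, and 16 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.00026; adjusted p = 0.25 with an estimated correlation), with Sdf2l1 higher by 2.21 and Pdia4, a disulfide isomerase, by 1.95. Of 13 heat-shock genes 6 rose, and 7 when adjusted over the list alone (camera adjusted p = 0.0034; adjusted p = 0.40 with an estimated correlation), and the mitochondrial chaperone gene Hspd1 rose by 2.07 on the log2 scale. Beside these lists, the 3-prime to 5-prime ratio was 7-fold for Gapdh and 3.69-fold for Actb in resting cells against 3.46-fold and 1.35-fold in IL-15 NK cells.

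Some genes of NK receptors, NK transcription factors and tissue homing fell after IL-15. Of 24 receptor genes none rose, 6 fell and 18 did not pass, and 7 fell when adjusted over the list alone (camera adjusted p = 0.00053; adjusted p = 0.12 with an estimated correlation). Klrg1, an inhibitory receptor found on mature NK cells, fell by 2.36 on the log2 scale (limma adjusted p = 8.4e-05) and Klra8, the activating receptor Ly49H, by 1.09. Klra8 no longer passed with every gene tested (limma adjusted p = 0.060). Ncr1, the NK receptor NKp46, differed by -0.39 and did not pass (limma adjusted p = 0.23). Of 18 transcription factor genes 9 fell and 9 did not pass, and 9 fell when adjusted over the list alone (camera adjusted p = 0.00018; adjusted p = 0.12 with an estimated correlation), and Zeb2, a regulator of late NK maturation, fell by 2.99. Of 18 homing and adhesion genes 12 fell, 1 rose and 5 did not pass, and 13 fell when adjusted over the list alone (camera adjusted p = 6.8e-05; adjusted p = 0.15 with an estimated correlation). Klf2, a transcription factor that sustains lymphocyte egress, fell 11-fold, S1pr5, a sphingosine phosphate receptor needed for NK egress, fell 9.08-fold and the chemokine receptor gene Cxcr4 fell by 2.45 on the log2 scale. In the same comparison 10 of 14 B-cell and 10 of 11 macrophage markers fell, with list medians of -2.64 and -2.21, and the 3-prime to 5-prime ratio of Gapdh was lower, at 3.46-fold against 7-fold. Of the genes that fell, 5 of 6 receptor genes, 7 of 9 transcription factor genes and 9 of 12 homing genes were not brighter in splenocytes than in resting NK cells.

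More interferon-response and immediate-early genes fell than rose after IL-15. Of 24 interferon-response genes 15 fell, 1 rose and 8 did not pass, and 16 fell and 3 rose when adjusted over the list alone (camera adjusted p = 9.6e-05; adjusted p = 0.12 with an estimated correlation). Rsad2, an antiviral enzyme, was at least 13-fold lower and Ifit3 at least 5.06-fold lower, with 2 and 1 of 3 IL-15 NK arrays above the floor. Of the 15 that fell, 4 were not brighter in splenocytes than in resting NK cells, and the B-cell and macrophage lists had medians of -2.64 and -2.21 in the same comparison, in which the 3-prime to 5-prime ratio of Gapdh went from 7-fold to 3.46-fold. Of 25 immediate-early genes, which are induced within minutes of a stimulus, 14 fell, 4 rose and 7 did not pass, and 15 fell and 4 rose when adjusted over the list alone (camera adjusted p = 0.0025; adjusted p = 0.50 with an estimated correlation). Besides Fos, Klf4 fell by 3.58 on the log2 scale, and Fosb, at the floor on all 3 IL-15 NK arrays, was at least 8.12-fold lower, though with every gene tested Fosb no longer passed (limma adjusted p = 0.084). The bound for Fosb was 5.05-fold without resting NK replicate 1 and 12.9-fold without resting NK replicate 3, with too few arrays above the floor for a test. Of the 14 that fell, 12 were not brighter in splenocytes than in resting NK cells. The immediate-early genes differed between the resting arrays, with a mean deviation from the resting mean of 0.51, 0.31 and -0.82 on the log2 scale in replicates 1, 2 and 3, where the B-cell markers deviated by 0.65, 0.65 and -1.30. Of 16 genes of the BCL2 family of apoptosis regulators 2 rose and 4 fell, as when adjusted over the list alone (camera adjusted p = 0.52).

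Most tested markers of B cells and macrophages were also lower in IL-15 NK than in resting NK cells. Of 14 B-cell markers tested, 10 fell, or 11 when adjusted over the list alone, with a median log2 difference of -2.64 (camera adjusted p = 7.0e-05; adjusted p = 0.34 with an estimated correlation). Of 11 macrophage and monocyte markers, 10 fell, as when adjusted over the list alone, with a median of -2.21 (camera adjusted p = 3.2e-06; adjusted p = 0.11 with an estimated correlation). Lyz1, a lysozyme gene, was at least 34.4-fold lower, and Mpeg1, which encodes a pore-forming protein of macrophages, at least 5.46-fold lower, both at the floor on all IL-15 NK arrays. Without resting NK replicate 1 the bound for Lyz1 was 69.5-fold, with too few arrays above the floor for a test. The B-cell markers stood at a median of 10.8%, 11.4% and 1.83% of the splenocyte level on resting replicates 1, 2 and 3, and at 0.876% to 1.10% on the IL-15 NK arrays. Cd22, an inhibitory coreceptor of B cells, had a mean log2 signal of 11.39 ± 1.51 in resting and 8.20 ± 0.36 in IL-15 NK cells (SD, n = 3 each). Its difference was -3.20 on the log2 scale, and without resting NK replicate 3 it was -4.07. With every gene tested Cd22 no longer passed (limma adjusted p = 0.099). Of 12 T-cell markers 4 fell, as when adjusted over the list alone (camera adjusted p = 0.023; adjusted p = 0.17 with an estimated correlation). Without resting NK replicate 2 the T-cell list did not pass (camera adjusted p = 0.075). The lists of plasma cell, neutrophil, dendritic cell, erythroid, platelet and stromal markers did not pass, with camera adjusted p from 0.23 to 0.68, although the plasma cell list passed without resting NK replicate 3 (camera adjusted p = 0.016).

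**Figure D3:**
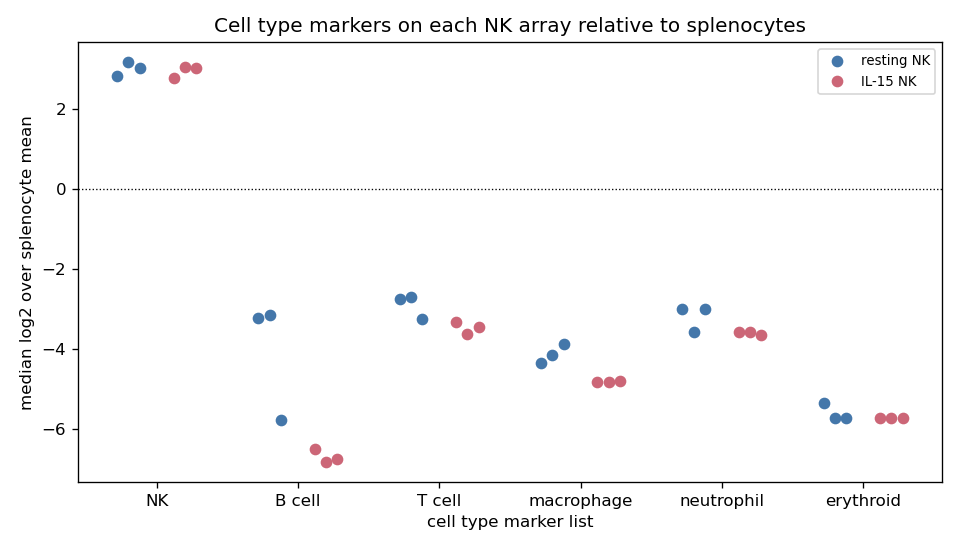
Median log2 difference from the splenocyte mean of 6 marker lists on each NK array; each point is 1 array. B-cell markers lay at -3.22, -3.14 and -5.77 on resting NK replicates 1, 2 and 3 and between -6.83 and -6.51 on IL-15 NK arrays, while NK markers lay between 2.77 and 3.17 on all 6.

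Comparing resting NK cells with splenocytes asks which transcripts mark NK cells before any stimulation. Prf1 was 64.2-fold higher in resting NK cells, with a mean log2 signal of 16.28 ± 0.28 (SD, n = 3) against 10.27 ± 0.40 (SD over 4 chips of 2 biological samples; limma adjusted p = 2.3e-06). A second, dimmer probe set of Prf1, not tested between NK groups because too few NK arrays lay above the floor, was lower in resting NK cells by a log2 difference of -0.74 (limma adjusted p = 0.023). Gzmb was 15.8-fold higher (limma adjusted p = 1.3e-05), Gzma 7.02-fold higher (limma adjusted p = 5.7e-05) and Ifng 57.2-fold higher (limma adjusted p = 6.5e-06). Gzma lay near the top of the signal range in NK cells, and whether this compressed its fold was not tested. S1pr5 was 67.3-fold and Klra8 38.1-fold higher. All 13 NK markers were higher, also when adjusted over the list alone, with a median log2 difference of 3.01 (camera adjusted p = 1.2e-11; adjusted p = 0.029 with an estimated correlation). Of 19 cytotoxic granule genes 16 were higher and 1 lower, the same as adjusted over the list alone (camera adjusted p = 1.6e-09; adjusted p = 0.053 with an estimated correlation). Of 26 NK receptor genes 17 were higher and 3 lower, and 18 were higher when adjusted over the list alone (camera adjusted p = 1.9e-08; adjusted p = 0.029 with an estimated correlation). Of 18 NK transcription factor genes 12 were higher and 2 lower, and 13 were higher when adjusted over the list alone (camera adjusted p = 2.7e-05; adjusted p = 0.029 with an estimated correlation). Eomes and Tbx21, the T-box factors of NK cells, were higher by 4.42 and 4.05 on the log2 scale. Of 19 homing genes 10 were higher and 4 lower, as when adjusted over the list alone (camera adjusted p = 0.0072; adjusted p = 0.18 with an estimated correlation).

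Most tested markers of B cells, T cells, macrophages, neutrophils and erythroid cells were lower in resting NK cells. All 20 macrophage markers were lower, also when adjusted over the list alone, with a median log2 difference of -4.08 (camera adjusted p = 2.8e-13; adjusted p = 0.029 with an estimated correlation). Of 20 B-cell markers 19 were lower, and 20 when adjusted over the list alone (camera adjusted p = 2.2e-07; adjusted p = 0.22 with an estimated correlation). Of 18 T-cell markers 14 were lower and 1 higher, as when adjusted over the list alone (camera adjusted p = 4.5e-06; adjusted p = 0.053 with an estimated correlation), and Cd3e, a chain of the T-cell receptor complex, was at least 38.7-fold lower, above the floor on 1 of 3 resting NK arrays. All 14 neutrophil markers were lower, also when adjusted over the list alone (camera adjusted p = 8.1e-09; adjusted p = 0.067 with an estimated correlation), and S100a9, above the floor on 1 of 3 resting NK arrays, was at least 258-fold lower. Of 12 erythroid markers 11 were lower and 1 higher, as when adjusted over the list alone (camera adjusted p = 4.3e-10; adjusted p = 0.053 with an estimated correlation). Slc4a1, the red cell anion exchanger, was at least 348-fold lower, at the floor on all resting NK arrays. In all, 4993 of 12938 genes differed in limma at an adjusted p under 0.05, 2212 higher and 2781 lower in resting NK cells, and at least 2-fold differences were found in 1411 higher and 2082 lower genes. Under quantile normalization the balance turned, with 2515 higher and 2442 lower. NK samples were amplified by a 2-cycle and splenocytes by a 1-cycle protocol, so every difference between them is also a difference of protocol. The 3-prime to 5-prime ratio of Gapdh was 7-fold in resting NK cells and 1.1-fold in splenocytes, and the geometric mean over 4 added poly-A controls was 12.7-fold and 1.73-fold. Where each probe set lies in its transcript was not analysed here. With the 4 splenocyte chips averaged to 1 sample, 3224 genes differed.

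Comparing IL-15 NK cells with splenocytes asks the same of activated cells. Gzmb was 39.8-fold higher in IL-15 NK cells (limma adjusted p = 3.1e-06) and Prf1 50.2-fold higher (limma adjusted p = 1.9e-06), with the dimmer probe set of Prf1 at -0.83 on the log2 scale (limma adjusted p = 0.013). Gzma was 4.90-fold higher (limma adjusted p = 0.00015), Ifng 26.7-fold higher (limma adjusted p = 1.5e-05) and Gzmc at least 22.8-fold higher (limma adjusted p = 0.00014). For Gzma and Gzmb the same open question of compression near the top of the signal range applies. Clnk, an adaptor of immunoreceptor signals, was at least 57-fold higher and Il12rb1 at least 20.4-fold higher, with 2 and 3 of 4 splenocyte chips above the floor. All 13 NK markers were higher, also when adjusted over the list alone (camera adjusted p = 4.8e-10; adjusted p = 0.059 with an estimated correlation), and 15 of 20 cytotoxic granule genes were higher and 1 lower, as when adjusted over the list alone (camera adjusted p = 2.1e-08; adjusted p = 0.059 with an estimated correlation). All 20 B-cell markers (camera adjusted p = 2.9e-09; adjusted p = 0.19 with an estimated correlation) and all 20 macrophage markers (camera adjusted p = 4.7e-14; adjusted p = 0.059 with an estimated correlation) were lower, also when adjusted over each list alone. Cd74, the invariant chain of antigen presentation, was 429-fold lower. Of 25 NK receptor genes 17 were higher and 3 lower, as when adjusted over the list alone (camera adjusted p = 4.1e-05; adjusted p = 0.059 with an estimated correlation). Of 19 homing genes 8 were higher and 9 lower, as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.97), its median of 0.03 and mean of -0.53 differing in sign. Of 12465 genes tested, 5524 differed in limma at an adjusted p under 0.05, 2596 of them higher and 2928 lower, and at least 2-fold differences were found in 1720 higher and 2170 lower genes. Under quantile normalization the balance turned, with 3058 higher and 2335 lower. Amplification differed here in the same way as for resting NK cells, and the 3-prime to 5-prime ratio was 3.46-fold in IL-15 NK cells and 1.1-fold in splenocytes for Gapdh, and 8.55-fold and 1.73-fold over the poly-A controls.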

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

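The tests of background, of immediate-early genes and of the poly-A controls were chosen after the results they bear on were seen, while the tests of shared variance among markers and of probe set gaps were written down first. Splenocyte chips were checked for a chip far from the other 3 in 99 named genes, and 3 genes had one, where chance gives about 1 in 20 groups one. Lta had a log2 signal of 10.04 on splenocyte replicate 1 against a mean of 10.62 on the others, a gap of 0.883 of the range. Rps27 had 10.24 on splenocyte replicate 4 against 11.68, a gap of 0.915 of the range. Rsad2 had 15.68 on splenocyte replicate 2 against 16.60, a gap of 0.861 of the range. In data outside the gene tests, the 18S ribosomal RNA control probe sets were 17.6-fold brighter on NK arrays than on splenocyte arrays. NK samples were amplified by a 2-cycle and splenocyte samples by a 1-cycle procedure, so cell type and protocol cannot be told apart here. Of 4130 probe sets without a gene symbol here, 1176 changed between IL-15 NK and resting NK cells, 1008 of them lower. Over all probe sets, 51.1% to 56.5% of signals lay above the floor on IL-15 NK arrays against 57.8% to 61.7% on resting NK arrays.

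B-cell and macrophage markers were present on resting NK arrays and lower after IL-15. Higher background of dim probe sets on the resting arrays is argued against, since genes of unrelated tissues differed by a median of -0.34 over 19 genes tested while the B-cell markers differed by -2.64 and the macrophage markers by -2.21. B-cell markers moved together between the resting arrays: 70% of their variance was common to all 12 markers, against a 95th percentile of 29.5% in 10000 matched gene sets. The sets were matched on mean and spread, not on being regulated together, so this does not single out 1 cause. Joint movement was predicted if other spleen cells or their RNA were carried into resting samples in differing amounts. Yet the sort took only NK1.1-positive, CD3-negative cells. However, macrophage markers deviated by -0.46, 0.01 and 0.45 on resting NK replicates 1, 2 and 3, where B-cell markers deviated by 0.65, 0.65 and -1.30. T-cell markers shared 2.5%, the 17 percentile of matched sets, over the 9 above the floor on all 3 resting arrays. Over 18 T-cell markers the median was 14.7%, 15.2% and 10.6% of the splenocyte level on replicates 1, 2 and 3. There 4, 3 and 8 lay at the floor. The 10 plasma cell markers were also lowest on replicate 3, at 10.2% against 19.2% and 24.9%. Carry-over of all spleen cells in 1 common proportion would move the lists together, so the macrophage values argue against that form of it. The T-cell values do not decide it, since the shared variance leaves out markers that reached the floor. Cd74, an abundant B-cell transcript, had a mean log2 signal of 10.66 ± 1.34 in resting NK cells (SD, n = 3 arrays) against 16.84 in splenocytes, and Lyz2, an abundant macrophage transcript, had 10.07 ± 1.07 (SD, n = 3 arrays) against 15.36. Without resting NK replicate 3 the difference of Cd74 went from -6.19 to -5.41, and without resting NK replicate 1 that of Lyz2 went from -5.29 to -4.68. None of the 20 markers of either list is in another list, and 9 to 11 B-cell and 15 or 16 macrophage markers lay at the floor on IL-15 NK arrays. For macrophage markers 28.2% was common, the 94.1 percentile of matched sets, so for them the test leaves carry-over in differing amounts open. Transcripts made by the NK cells themselves and lowered by IL-15 remain an untested biological explanation for both lists.

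Immediate-early transcripts were higher on resting NK than on IL-15 NK arrays. Of the 14 that fell, 2 were brighter in splenocytes than in resting NK cells by their means. Fos, Fosb, Jund, Ier2, Klf6 and Tnfaip3 passed as higher in resting NK cells and Btg2 as lower, while the others did not pass (limma adjusted p from 0.078 to 0.63). For the genes that passed as higher, this argues against carry-over of spleen cells at the transcript levels of the splenocyte samples. The amplification protocol differed between the 2 sides of that comparison. Of the variance of the immediate-early genes between resting arrays, 57.9% was common to all 25 genes, against a 95th percentile of 13.2% in matched gene sets. As for the B-cell markers, resting NK replicate 3 was the low one. The sets were matched on mean and spread, not on answering the same stimuli, so this cannot tell carry-over from differing handling of the NK cells. Carried-over cells whose transcripts changed during handling also stay open. Handling before lysis, 24 h of culture and IL-15 cannot be told apart, because no sample of NK cells cultured without IL-15 was analysed here. Heat-shock genes, which also answer handling, give it no support: of 13 none was called higher on resting arrays and 6 were higher after IL-15, with a list median of 0.67 (camera adjusted p = 0.0034; adjusted p = 0.40 with an estimated correlation), and Hspa1b, Dnajb1, Bag3 and Hspb1, the 4 lowest of them, picked after the values were seen, had a median of -0.07, but culture or IL-15 may raise such genes too, so handling is not excluded.

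The 3-prime to 5-prime signal ratio of the control probe sets was larger on resting NK than on IL-15 NK arrays, by a log2 difference of 1.02 for Gapdh and 1.45 for Actb (exact permutation p = 0.1 for each, the smallest possible with 3 against 3 arrays). The 4 poly-A controls added to the RNA were higher by 0.57 on average, and single controls ranged from 0.08 to 0.89. The average was just past the bound set for poorer synthesis of long copies in the labelling, but only with resting NK replicate 2 included. The mean log2 ratios were 3.33, 4.13 and 3.56 on resting NK replicates 1, 2 and 3, and 2.96 to 3.17 on IL-15 NK arrays. Every resting array was thus higher, which goes weakly with that explanation. The 3-prime log2 signal of these controls was also brightest on resting NK replicate 2, at 15.03 against 12.9 and 12.6 on the other resting arrays. On IL-15 NK replicates 1, 2 and 3 it was 12.1, 12.58 and 11.66, lower than on every resting array. The hybridization controls were likewise brighter on every resting array, at 13.51 to 14.2 against 13.12 to 13.31. Whether this shift entered the folds between the groups was not tested. Shorter RNA over all genes is argued against only as far as the dimmer of a gene's probe sets lies upstream, which was not checked: over 3969 genes the gap between probe sets differed by -0.07, the opposite of what it needs. On splenocyte arrays, labelled with 1 amplification cycle, the ratio was 1.1-fold for Gapdh and 1.73-fold over the poly-A controls, against 7-fold and 12.7-fold on resting NK and 3.46-fold and 8.55-fold on IL-15 NK arrays. No biological explanation was tested.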

How the results depend on the processing

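The setting that left out genes brighter in splenocytes and the one that left out markers of other cell types were chosen after seeing the data; they gave 926 and 1351 lower genes in IL-15 NK against 1384. The count of 3003 genes changed between IL-15 NK and resting NK was 1646 without a filter on dim genes, 6373 over all probe sets singly, 1612 at an adjusted p under 0.01, and 1963 to 3241 with 1 array left out, the lowest without IL-15 NK replicate 3. The 4993 genes of resting NK against splenocytes became 10885 over all probe sets, 3219 at an adjusted p under 0.01 and 3224 with the chips averaged to 1 sample, with 4441 to 5188 when 1 array was left out. The 5524 of IL-15 NK against splenocytes became 11501 over all probe sets, with 4616 to 5221 when 1 array was left out. More probe sets than genes, a stricter threshold and 1 sample in place of 2 account for those counts by construction; for the filter and for the counts with an array left out, which went up without resting NK replicate 2, the cause was not tested. Quantile normalization moved the median of all genes from -0.098 to 0.11 in IL-15 NK against splenocytes and from -0.057 to 0.05 in resting NK against splenocytes, and turned the balance of calls to 3058 higher and 2335 lower and to 2515 higher and 2442 lower. In IL-15 NK against splenocytes it also turned with common median scaling (2856 higher, 2679 lower), the 60th percentile filter (2629 and 2544) and no floor (2614 and 2608). All probe sets singly turned the balance of IL-15 NK against resting NK to 2828 higher and 3545 lower. Rps24, lower in IL-15 NK than in splenocytes, reversed to 1.85 on the log2 scale with another probe set; the cause was not tested. Of 125 named genes called in IL-15 NK against resting NK, 45 lost the call under some setting, 42 of them without the filter, 18 with an array left out and 4 under another normalization, and 0 reversed; 6 of the 125 had no test without some array, for too few arrays above the floor, and are not counted as lost there. In the splenocyte comparisons 8 of 77 and 5 of 77 lost it. List calls were lost with an array left out for 1 of 20, 2 of 16 and 1 of 12 lists, in the order of the report, and under another normalization for 0, 3 and 1; calls were gained under some setting for 1, 1 and 3 lists, and 0 reversed.

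The design text speaks of 3 pairs of NK samples without saying that replicate numbers mark them. Deviations of same-numbered arrays from their group means correlated at 0.103, 0.281 and 0.066, all positive. Those of differently numbered arrays ran from -0.222 to 0.154, the highest for IL-15 NK replicate 1 with resting NK replicate 3. Pairing by number therefore stays open. The main fit had no block because no label says what the numbers mark. With the replicate number as a block 3421 genes changed, and none of 132 named genes or 33 lists changed its call.

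Of the 10 splits of the 6 NK arrays into 3 and 3, only the real one, 1 split, reached 3003 genes, and the highest of the others called 0 in limma, with 114 to 519 genes at an unadjusted p under 0.05 in the others. With 10 splits the share cannot be under 0.05. Dim genes are limited by background, since 5.2% to 24% of the values of genes of unrelated tissues lay above the floor per array.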

Other observations

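Families of genes that share a symbol stem were tested in IL-15 NK against resting NK after the data had been seen, without a prior hypothesis. Of 183 families with at least 8 tested members, 23 passed (camera adjusted p under 0.05), and 0 passed with an estimated correlation, where 11 had an unadjusted p under 0.05. The family medians given here kept their sign under quantile normalization and common median scaling. Among mitochondrial ribosomal protein genes, 16 of 47 large-subunit genes (Mrpl) were higher and none lower, with a median log2 difference of 0.52 (camera adjusted p = 5.1e-05; adjusted p = 0.58 with an estimated correlation), and 14 of 29 small-subunit genes (Mrps) were higher and none lower, with a median of 0.60 (camera adjusted p = 5.4e-05; adjusted p = 0.56 with an estimated correlation). Of 14 genes of mitochondrial inner membrane import (Timm) 9 rose, with a median of 1.04 (camera adjusted p = 0.0021; adjusted p = 0.56 with an estimated correlation), and of 9 RNA exosome genes (Exosc) 6 rose, with a median of 1.05 (camera adjusted p = 0.00065; adjusted p = 0.56 with an estimated correlation).

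Of 11 Krueppel-like transcription factor genes (Klf), 10 fell and none rose, with a median log2 difference of -1.43 (camera adjusted p = 9.0e-05; adjusted p = 0.56 with an estimated correlation). This family includes Klf2, Klf4, Klf6 and Klf12, which also belong to lists described in the report. Of 14 phosphodiesterase genes (Pde) 5 fell, with a median of -0.63 (camera adjusted p = 0.019; adjusted p = 0.56 with an estimated correlation).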
